A study of Mus musculus with 16 samples.

How the data were processed

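RNA was sequenced from nuclei of the colonic muscle layer and myenteric plexus of C57BL/6 mice kept free of specific pathogens. Per the labels' protocols, mice received an AAV9 vector carrying a nuclear-envelope EGFP under a CaMKII promoter 5 weeks before the nuclei were isolated. The aryl hydrocarbon receptor (AhR) agonist 3-methylcholanthrene, or corn oil as control, was injected intraperitoneally 14 hours before isolation. Nuclei were gated on DAPI, and EGFP-positive (neuronal) and EGFP-negative (non-neuronal) nuclei were sorted apart. The labels give 4 groups of 4 libraries, 16 libraries in all. They do not give the dose, and they do not say whether the 4 libraries of a group come from separate mice or from pools. The p-values therefore measure only the spread between these samples.

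Per the labels' protocols, nuclear RNA was turned into cDNA with the Ovation RNA-Seq System V2 and sheared to 200 bp. Libraries were made with 7 PCR cycles and sequenced as 75 bp single-end reads on a HiSeq4000. The deposited table holds an expected count for each of 51912 Ensembl genes in each library, which the authors made with RSEM. The column headers of that table carry a project name about wild-type and AhR knockout mice, while the library names inside them, like the labels, give agonist or control. Groups were taken from the labels, and the project name was not explained in the sources used here. Per the submitters' processing notes, RSEM 1.3.0 and STAR 2.5.2 were used with the mouse build GRCm38, and DESeq2 1.10.1 is also named. The annotation release and the strand setting are not given in the sources used here. The deposited values are not scaled to library size, and between 89.2% and 94.3% of all values per library, zeros included, are whole numbers. The share among nonzero values is lower. A gene that shares exons or near-identical sequence with another can carry divided or uncertain counts. Symbols and GRCm38 positions were taken from the GENCODE M21 annotation by Ensembl identifier. A symbol was found for 51633 identifiers and none for 279, and 143 symbols belong to several identifiers.

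Expected counts were rounded to whole numbers. Each comparison was fitted in edgeR 4.0.16 under R 4.3.3 with TMM scaling, robust quasi-likelihood dispersions and a two-sided quasi-likelihood F-test. Genes were kept by edgeR's filterByExpr by group, with a minimum count of 10 and a minimum total count of 15. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. The standard error (SE) of a log2 fold change is its size divided by the square root of its F statistic. Levels of genes are given as TMM-scaled CPM (counts relative to the scaled library size), as mean ± SD over the 4 libraries of a group. Summed levels of lists are CPM by library size without TMM scaling, and so are the carry-over values of the closing section unless TMM is named. The 5 comparisons are the agonist response in each population, the difference of the agonist response between populations, and neuronal against non-neuronal nuclei under each treatment. The difference was fitted over all 16 libraries and the others over 8 libraries each. The CPM values of a gene therefore differ between those fits, and levels are to be compared within 1 fit. Levels of the fixed AhR genes were also compared by two-sided exact permutation tests, 17 tests in 1 family, for which 4 against 4 libraries cannot give a p under 0.0286.

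Gene lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01. A total of 30 lists were fixed, and a list was tested where at least 5 members passed the count filter. Adjusted p-values run over the lists of 1 comparison. The lists cover AhR target genes, AhR signalling components, oxidative stress (NRF2) genes, glutathione transferases and glucuronosyltransferases, immediate early, heat shock, circadian clock, glucocorticoid-responsive, p53 target and cholesterol synthesis genes, interferon-stimulated genes and inflammatory mediators. They also cover pan-neuronal, enteric transmitter and peptide, voltage-gated and potassium channel, neurotransmitter receptor, and synaptic vesicle and release genes. Markers of other cells cover enteric glia, smooth muscle, interstitial cells of Cajal, fibroblasts and PDGFRA-positive cells, mesothelium, blood and lymphatic endothelium, pericytes, macrophages, lymphocytes and epithelium, with mitochondrially encoded and ribosomal protein genes as signs of RNA outside the nucleus. The smooth muscle, fibroblast, pericyte, interstitial cell and endothelial lists name cells that the sampled muscle layer itself holds.

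Comparisons, tests, lists, most alternatives and the rule for named genes were chosen before the data were examined. By that rule, the AhR genes Cyp1a1, Cyp1a2, Cyp1b1, Ahrr, Tiparp, Nqo1, Aldh3a1, Ahr and Arnt are named in the agonist comparisons, and 12 cell-type markers in the comparisons between populations. Up to 10 genes with the largest change in each direction follow, among genes past the threshold with an average log2 CPM of at least 1, a symbol other than a predicted gene, and groups that do not overlap. Where none passes in a direction, the 5 with the smallest p are given as values that did not pass. Up to 4 members with the smallest p are named in each list described. A few genes that the rule names, markers and list members, are not reported. Genes named outside the rule are said to be chosen after their values were seen.

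The total per library ranged from 2663738 to 4902303 counts. A count of 3 in a library, about the upper 95% counting limit for a count of 0, stands for 0.612 to 1.13 CPM. Where a group's libraries all hold 0, a fold is given as a lower bound against 3 counts over the group. Where 1 to 3 counts were seen, the ratio has a 95% counting interval. Reads carry no molecular identifiers, so these intervals and floors cover counting error only.

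The alternatives were DESeq2 1.42.0 with its own filtering, DESeq2 size factors inside edgeR, library size without scaling, no count filter, a mean of at least 5 CPM, limma voom with sample quality weights, and a test against a 1.5-fold change. Others placed all 4 groups in 1 fit, left out mitochondrially encoded and ribosomal protein genes, took the replicate number as a block, or left out each library in turn. For lists, a correlation estimated per list and limma's fry were added. Alternatives chosen after seeing the data left out libraries with over 30% mitochondrial counts, also together with the library neuronal agonist 1, or ran DESeq2 on the genes kept by filterByExpr. DESeq2 was thus run from 2 starting gene sets. No library was left out of the results as reported, and no sample was unassigned. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.

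The tests were tested on simulated data with the per-gene spread of each comparison, in which 67, 67 and 66 genes changed 2-, 4- and 16-fold. A further list of 13 genes changed 4-fold. Genes were drawn independently, so spread shared by the genes of a library was not simulated, and the real tests may perform otherwise. In a simulated neuronal agonist comparison 2, 16 and 52 of the genes changed 2-, 4- and 16-fold outside that list were called. In a simulated non-neuronal agonist comparison 0, 4 and 24 were called. For the difference of responses 0, 0 and 13 were called, for the populations in control mice 3, 21 and 50, and in agonist mice 1, 1 and 26. Between 1 and 3 unchanged genes were called per comparison.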

Results

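The series measured nuclear RNA of the mouse colon in 4 groups of 4 libraries. Neuronal nuclei carried the EGFP tag of the viral vector, and non-neuronal nuclei came from the same tissue without it. The agonist, 3-methylcholanthrene, is a polycyclic aromatic hydrocarbon that binds the aryl hydrocarbon receptor (AhR), a transcription factor that switches on detoxifying enzymes. The total count was 4434251, 3887826, 3184189 and 2887416 in the neuronal agonist libraries 1 to 4. It was 2982245, 3289193, 3521090 and 3080493 in the neuronal control libraries. The non-neuronal agonist libraries held 4902303, 3559460, 4729552 and 4206703 counts, and the non-neuronal control libraries 3149047, 2663738, 4411652 and 3873881.

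Transcripts of neurons made up much more of the neuronal libraries than of the others. The summed level of the 30 pan-neuronal genes was 7596 ± 452 CPM (SD, n = 4) in neuronal control and 7478 ± 330.0 CPM in neuronal agonist libraries. In non-neuronal libraries it was 616 ± 302 CPM with corn oil and 446 ± 209 CPM with agonist. Smooth muscle genes summed to 13858 ± 9235 CPM in non-neuronal control and 8464 ± 4419 CPM in non-neuronal agonist libraries, against 1793 ± 720.2 and 1377 ± 294 CPM in the neuronal ones. Epithelial genes, from the mucosa beside the muscle layer, summed to 6528 ± 4080 CPM in non-neuronal control and 2787 ± 1261 CPM in non-neuronal agonist libraries, and Muc2 alone made up 87.3% and 66.4% of these sums. Mitochondrially encoded transcripts, which lie outside the nucleus, took 42.8%, 33.3%, 21.8% and 10.3% of the counts in non-neuronal agonist libraries 1 to 4. They took 11.2%, 14.3%, 26.3% and 16.1% in the non-neuronal control libraries, and 3.10% ± 1.52 and 3.37% ± 1.87 in neuronal agonist and control libraries (SD, n = 4). Genes with a count numbered 17293 to 21247 in neuronal agonist and 21063 to 26379 in neuronal control libraries. They numbered 19683 to 22411 in non-neuronal agonist and 22958 to 27705 in non-neuronal control libraries, without overlap. Replicates differed by more than counting error, since the chi-square per degree of freedom between libraries of 1 group was at least 8.78. The log2 CPM of replicate libraries correlated across genes at 0.727 to 0.955, and genes are not independent replicates.

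**Figure D1:**
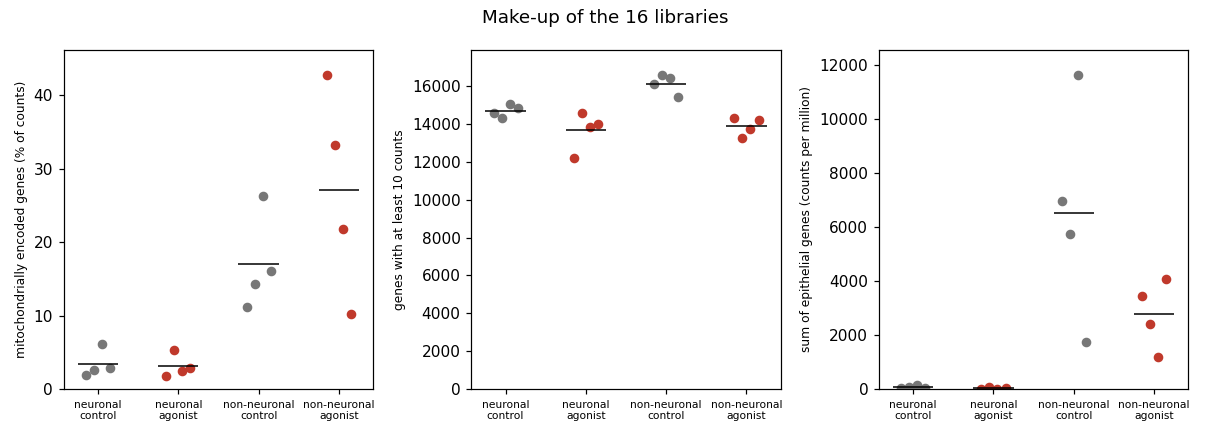
Each point is 1 library in its group of 4, and each line is the group mean; the panels give mitochondrially encoded counts in percent, the number of genes with at least 10 counts, and the summed level of epithelial genes in CPM. Mitochondrial counts reach 42.8% in non-neuronal agonist library 1, and epithelial genes reach 11653 CPM in non-neuronal control library 3.

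The comparison of neuronal with non-neuronal nuclei in control mice asks which genes mark the sorted populations. The named genes of neuronal identity were each more than 10-fold higher in the neuronal nuclei. Elavl4 (ENSMUSG00000028546), which encodes a neuronal RNA-binding protein, stood at 428 ± 60.7 CPM in neuronal and 29.4 ± 15.01 CPM in non-neuronal nuclei (SD, n = 4). Ret, the receptor for glial cell line-derived neurotrophic factor, stood at 240.0 ± 21.5 against 21.4 ± 13.6 CPM. Snap25, a protein of vesicle fusion, stood at 888 ± 147 against 82.3 ± 65.9 CPM. Myh11, the heavy chain of smooth muscle myosin, stood at 255 ± 178 CPM in neuronal and 4027 ± 2259 CPM in non-neuronal nuclei, and Kit (ENSMUSG00000005672), the receptor that marks interstitial cells of Cajal, at 3.32 ± 0.988 and 151 ± 52.7 CPM.

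Of 15285 genes tested, 1811 were higher and 2065 lower in the neuronal nuclei, or 2084 higher and 1679 lower with library size only. The log2 fold change was 3.86 for Elavl4 (SE 0.34, adjusted p = 8.19e-06), 3.48 for Ret (SE 0.41) and 3.43 for Snap25 (SE 0.45). It was -3.98 for Myh11 (SE 0.49), -3.54 for the smooth muscle actin Actg2 (SE 0.60), -4.52 for Pdgfra of fibroblast-like cells (SE 0.69), -5.49 for Kit (SE 0.42) and -3.37 for the endothelial gene Pecam1 (SE 0.71). The glial transcription factor Sox10 was lower in neuronal nuclei (-4.09, SE 1.13, adjusted p = 0.0164). Cx3cr1 of macrophages had 7 neuronal and 67 non-neuronal counts and was not tested. A share of 30.9% of genes had groups that did not overlap, where chance gives 2.86%. DESeq2 called 6716 genes, and all 4 groups in 1 fit called 2710 and left Sox10 at an adjusted p of 0.0741 (range over alternatives 0.000229 to 0.0741).

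Most genes named for the largest change had no counts in 1 population, so only a lower bound of the fold is known. Panx2, a pannexin channel, was at least 58.4-fold higher in neuronal nuclei, the galanin receptor Galr1 at least 40.2-fold, and the calcium-binding protein gene Necab2 at least 67.1-fold. Cpne7, Rnf208 and BC028471 were at least 29.7-, 27.3- and 35.7-fold higher. Pcdha6 was at least 169-fold higher, and it shares exons with the other alpha protocadherins. The antisense RNA Ppp2r2cos and the ribosomal pseudogenes Rpl10-ps4 and Rpl7a-ps9 were at least 63.8-, 39.9- and 25.5-fold higher. In the other direction, Ecscr, an endothelial surface protein, was at least 123-fold lower, the leukocyte integrin Itgam at least 96.0-fold and the immunoglobulin chain Ighm at least 102-fold. Ano9, of the anoctamin family, was at least 310-fold lower, Ttll10 at least 307-fold, Fam3b at least 164-fold, Tifa at least 136-fold, Clec2e at least 123-fold and Creb3l4 at least 108-fold. Ern2, a stress sensor of mucus-secreting cells, had 1 neuronal and 2031 non-neuronal counts, a ratio of 0.000443 with a counting interval from 1.12e-05 to 0.00247.

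By camera every neuronal list was higher in the neuronal nuclei of control mice, and each of these calls ended with an estimated correlation. Of 30 pan-neuronal genes 26 were higher, with a median log2 fold change of 3.06 and an adjusted p of 1.6e-13 (adjusted p = 0.0660 with an estimated correlation), among them Map2 (4.58) and Dlg2 (3.45). Of 19 enteric transmitter and peptide genes 13 were higher, with nitric oxide synthase Nos1 at 3.79 and the choline transporter Slc5a7 at 5.29 (median 2.57, adjusted p = 2.36e-07, and adjusted p = 0.0660 with an estimated correlation). Of 52 voltage-gated and potassium channel genes 31 were higher and 3 lower, with the sodium channel Scn2a at 4.44 and the potassium channel Kcnq3 at 4.59 (median 1.72, adjusted p = 9.68e-10, and adjusted p = 0.0555 with an estimated correlation). Of 45 neurotransmitter receptor genes 17 were higher and 1 lower, with the glutamate receptor Gria4 at 4.16 and the nicotinic receptor Chrna3 at 3.66 (median 1.28, adjusted p = 6.1e-06, and adjusted p = 0.0917 with an estimated correlation). Of 35 synaptic vesicle and release genes 25 were higher, with the scaffold Pclo at 4.32 (median 2.50, adjusted p = 2.01e-11, and adjusted p = 0.0676 with an estimated correlation). Of 18 cholesterol synthesis genes 5 were higher, among them Lss (1.48) and Sqle (1.36), with a median of 0.97 and an adjusted p of 0.0148, or an adjusted p of 0.305 with an estimated correlation.

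Markers of other cells were lower by camera. The medians were -3.38 for smooth muscle genes (20 of 21 lower, adjusted p = 2.01e-11), -4.13 for fibroblast and PDGFRA-cell genes (14 of 19, 1.37e-08) and -3.97 for blood endothelial genes (12 of 16, 6.36e-08). The adjusted p of these lists was 0.160, 0.135 and 0.0765 with an estimated correlation. The medians were -5.53 for lymphatic endothelial genes (6 of 9, 6.76e-05), -3.36 for pericyte genes (3 of 5, 0.0045), -5.76 for macrophage genes (10 of 12, 2.01e-09), -4.27 for lymphocyte genes (3 of 6, 0.00774) and -4.84 for epithelial genes (11 of 12, 1.37e-08). With an estimated correlation macrophage genes kept the call (adjusted p = 0.0161), and the adjusted p was 0.103 for lymphatic, 0.135 for pericyte, 0.174 for lymphocyte and 0.103 for epithelial genes. With genes absent from neuronal nuclei set at their bound, the macrophage median was -5.56. Examples are Col3a1 of connective tissue (-5.04), the vascular receptor Kdr (-6.79), the lymphatic receptor Lyve1 (-6.66), the macrophage receptor Mrc1 (-5.19) and the mucin Muc2 (-7.49). The glia list was lower as well (7 of 11 genes, median -3.18, adjusted p = 0.0180), as was the interstitial cell list (5 of 8, with Etv1 higher, median -3.14, adjusted p = 0.0203). Their adjusted p was 0.259 and 0.331 with an estimated correlation. Without non-neuronal control library 4 their adjusted p became 0.108 and 0.0566 (ranges over alternatives 1.74e-06 to 0.259 and 5.08e-06 to 0.331).

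Of the remaining lists in control mice, mitochondrially encoded genes were lower (10 of 12, median -2.60, adjusted p = 2.2e-07), as were ribosomal protein genes (15 of 32, -1.31, 1.19e-07). Their adjusted p was 0.135 and 0.0660 with an estimated correlation. Immediate early genes were lower (10 of 18, -1.72, 0.000155, and adjusted p = 0.0852 with an estimated correlation), with Fos at -2.19 and Jun at -2.92. Lower too were glutathione transferases and glucuronosyltransferases (5 of 11, -2.32, 0.00103) and glucocorticoid-responsive genes (4 of 9, -2.11, 0.0068), at an adjusted p of 0.135 and 0.103 with an estimated correlation. Lists of AhR target genes (adjusted p = 0.0810, 4 of 8 genes lower), AhR signalling components (0.647), oxidative stress genes (0.770), heat shock genes (0.770), clock genes (0.336), p53 target genes (0.579) and interferon-stimulated genes (0.0879, 5 of 16 lower) were not called by camera. With fry the AhR target list was called lower (adjusted p = 0.00177).

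In agonist mice the same comparison asks whether the populations stood apart as they did in control mice. Elavl4 stood at 302 ± 77.1 CPM in neuronal and 21.0 ± 37.1 CPM in non-neuronal nuclei (SD, n = 4), and Ret at 214 ± 70.0 against 7.35 ± 11.7 CPM. Myh11 stood at 178 ± 53.3 against 2899 ± 729.9 CPM, and Pdgfra at 1.91 ± 2.13 against 206 ± 113 CPM. Cyp1a1 (ENSMUSG00000032315), the AhR target that oxidises aromatic hydrocarbons, was lower in the neuronal nuclei of agonist mice, at 5.41 ± 2.29 against 80.2 ± 81.5 CPM (log2 fold change -3.89, SE 1.01, adjusted p = 0.0182).

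Of 14065 genes tested, 938 were higher and 980 lower in neuronal nuclei, or 1332 higher and 649 lower with library size only. The log2 fold change was 3.83 for Elavl4 (SE 1.06, adjusted p = 0.0287), 4.84 for Ret (SE 1.07) and 3.65 for Snap25 (SE 0.50). It was -4.03 for Myh11 (SE 0.33), -3.87 for Actg2 (SE 0.66), -6.71 for Pdgfra (SE 0.87), -4.21 for Kit (SE 0.97) and -4.36 for Pecam1 (SE 1.05, adjusted p = 0.0117). Sox10 (-4.89, SE 1.78, adjusted p = 0.0857) did not pass, and Cx3cr1 had 0 neuronal and 9 non-neuronal counts. A share of 21.6% of genes had groups that did not overlap, where chance gives 2.86%. DESeq2 called 4340 genes, no filter 3324, voom 2910 and all 4 groups in 1 fit 4590.

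Calls of some single genes in this comparison changed when 1 library was left out, with the direction kept. Elavl4 had an adjusted p of 0.0679 without neuronal agonist library 1, 0.0642 without 3 and 0.0693 without 4, and 0.0674 without the libraries over 30% mitochondrial counts (range over alternatives 3.61e-05 to 0.0693), where its log2 fold change was 3.68, 3.82, 3.99 and 2.96. Cyp1a1 had 0.0506 without neuronal agonist library 2, 0.0535 without non-neuronal agonist library 3 and 0.0651 without library 4 (range 0.00022 to 0.0651), with -3.90, -3.43 and -3.35. Pecam1 had 0.0678 (-3.41) and Sox10 0.0404 (-5.30) without non-neuronal agonist library 4 (ranges 3.18e-05 to 0.0678 and 0.0111 to 0.247). Of 13306 genes tested under both treatments, 716 were higher under both, where independence gives 115, and 770.0 were lower under both, where independence gives 114. No gene was called in opposite directions, and the 2 comparisons share no library.

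Among the largest changes in agonist mice, the synaptic adhesion gene Lrrtm1 was at least 109-fold higher in neuronal nuclei, the acid-sensing channel Asic1 at least 91.6-fold, the cation channel Trpc7 at least 91.3-fold and the transcription factor Mycn at least 90.2-fold. The dynein gene Dnah1, the ciliary gene Nphp4, Ankrd45 and Caly were at least 149-, 144-, 131- and 102-fold higher. Pcdha7 and Pcdha11, which share exons within their cluster, were at least 174- and 94.0-fold higher. Lower were the iron oxidase Heph (at least 419-fold), the alcohol dehydrogenase Adh1 (394), the interferon-induced GTPase Gbp4 (472), Adgrg3 (524), Tinag (504), Plac8 (365), Slfn4 (300.4) and Tmc5 (294), each at least by the fold given. Naip1 was at least 385-fold lower and belongs to a family of near-identical genes. Cyp3a13, a drug-metabolising enzyme, had 1 neuronal and 2723 non-neuronal counts, a ratio of 0.000295 with a counting interval from 7.47e-06 to 0.00165.

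The neuronal lists lay higher and the other-cell lists lower in agonist mice as well. Pan-neuronal genes were higher (18 of 29, median 3.65, adjusted p = 1.3e-13), with Map2 at 4.92. Transmitter and peptide genes were higher (7 of 18 with 1 lower, 2.14, 8.24e-07), with Nos1 at 4.81 and Vip at 3.86. Channel genes (20 of 54 with 2 lower, 2.21, 2.41e-09), receptor genes (18 of 45 with 2 lower, 1.86, 4.22e-07), synaptic genes (16 of 36 with 1 lower, 2.50, 2.38e-09) and cholesterol synthesis genes (5 of 17, 1.46, 0.000331) were higher too. Lower were glia (3 of 14, -3.06, 0.000688), smooth muscle (17 of 21, -3.87, 5.89e-13), interstitial cell (4 of 8, -3.21, 0.0134), fibroblast (12 of 18, -4.56, 7.54e-09), blood endothelial (10 of 14, -4.64, 8.81e-10), lymphatic (6 of 9, -6.54, 4.22e-07), pericyte (4 of 7, -4.27, 0.000302), macrophage (7 of 8, -5.67, 5.58e-09) and epithelial genes (10 of 13, -5.89, 8.81e-10). Of these, the interstitial cell and pericyte calls ended, at an adjusted p of 0.0595 and 0.0619 with an estimated correlation.

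Inflammatory mediators were lower in the neuronal nuclei of agonist mice (6 of 7, median -5.30, adjusted p = 1.81e-06), as were glucocorticoid-responsive genes (5 of 14, -3.48, 7.72e-07), interferon-stimulated genes (4 of 15, -2.50, 0.00295) and glutathione transferases and glucuronosyltransferases (8 of 11, -4.65, 1.3e-06). The interferon call ended, at an adjusted p of 0.0510 with an estimated correlation. Lcn2, an iron-binding protein of inflamed epithelium, had 0 neuronal and 677 non-neuronal counts. Immediate early (4 of 15, -1.65, 0.00116), mitochondrially encoded (11 of 13, -3.35, 3.27e-08), ribosomal protein (2 of 33, -1.99, 1.66e-07) and AhR target genes (4 of 9 lower with 1 higher, -2.56, 0.0267) were lower. These 4 calls ended, at an adjusted p of 0.0766, 0.0994, 0.0776 and 0.134 with an estimated correlation. AhR signalling (0.747), oxidative stress (0.283), heat shock (0.468), clock (0.283) and p53 genes (0.385) were not called. Scaling shifted the median of all genes between populations from -0.11 with TMM to 0.11 with library size only in control mice, and from -0.15 to 0.43 in agonist mice.

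**Figure D2:**
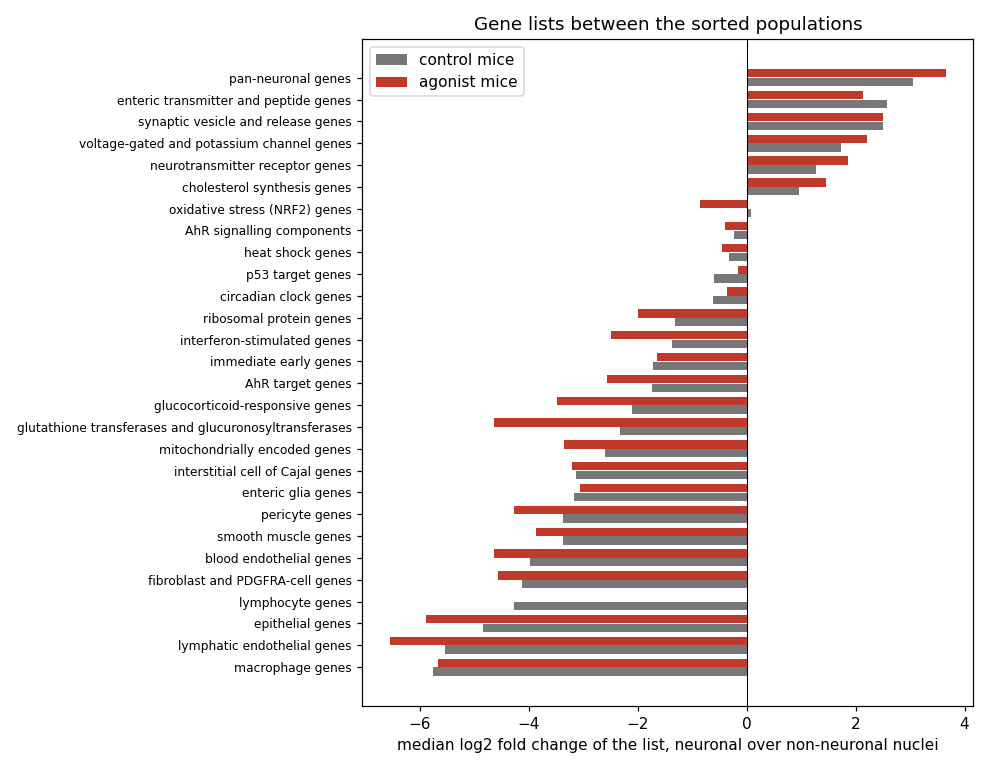
Bars show the median log2 fold change of each gene list in neuronal over non-neuronal nuclei, grey for control mice and red for agonist mice, 4 libraries per group. Pan-neuronal genes reach 3.06 and 3.65, and lymphatic endothelial genes -5.53 and -6.54.

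The agonist response in neuronal nuclei asks which genes of enteric neurons change 14 hours after AhR activation. Several AhR genes stood higher in the libraries from agonist mice. Cyp1a1 (chromosome 9, 57687928 to 57703824, GRCm38) was at 3.00, 7.29, 7.69 and 9.55 CPM in the agonist libraries and at 0 in all 4 controls, 92 against 0 counts and at least 30.1-fold higher. Non-neuronal agonist nuclei held 75.1 ± 76.4 CPM of it. Ahrr (ENSMUSG00000021575, chromosome 13, 74211118 to 74292331), the repressor that AhR induces against itself, stood at 68.0 ± 4.70 CPM with agonist and 9.70 ± 6.16 CPM with corn oil (SD, n = 4). Tiparp (ENSMUSG00000034640, chromosome 3, 65528410 to 65555518), an ADP-ribosyltransferase that also restrains AhR, stood at 99.7 ± 41.9 against 43.2 ± 7.32 CPM. Pan-neuronal genes, by contrast, lay near 0, with 15 of 30 above it and a median log2 fold change of -0.01, or 0.012 with DESeq2 size factors.

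No gene passed the threshold over all 14182 genes tested by edgeR, in which the smallest adjusted p was 0.527. Cyp1a1 was removed by the count filter in this comparison, so it is not among the genes or list members tested. DESeq2 with its own filtering called Cyp1a1 (log2 fold change 6.97, adjusted p = 0.00156). A total of 711 genes had an unadjusted p under 0.05, where 709.1 are given by chance, 523 of them higher and 188 lower. DESeq2 called 24 genes, or 9 on the genes edgeR kept, and voom with sample weights called 3, Abca1, Ahrr and Specc1. Without a count filter edgeR called 152. The groups did not overlap for 3.62% of genes, where chance gives 2.86%. The median SE of a log2 fold change was 0.62.

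The log2 fold change of Ahrr was 2.81 (SE 0.51, adjusted p = 0.574), with every agonist library above every control. Its adjusted p was 0.000224 by DESeq2, 9.79e-05 by DESeq2 on the genes edgeR kept and 0.0198 by voom (range over alternatives 9.79e-05 to 1). Tiparp had 1.21 (SE 0.38, adjusted p = 0.903), and 3 of its 4 agonist libraries lay above all controls. Adjusted over the list alone, Ahrr (0.000607) and Tiparp (0.0189) passed among the 5 AhR target genes tested. Cyp1b1 (ENSMUSG00000024087, chromosome 17, 79701537 to 79715061), a related oxidising enzyme, stood at 16.2 ± 10.8 against 5.34 ± 3.40 CPM (1.59, SE 0.86). Ahr itself (ENSMUSG00000019256, chromosome 12, 35497974 to 35535038) stood at 108 ± 43.8 against 71.0 ± 8.87 CPM (0.61, SE 0.32), and its partner Arnt (ENSMUSG00000015522, chromosome 3, 95434388 to 95497240) at 142 ± 17.4 against 149 ± 21.5 CPM (-0.07, SE 0.23, and 0.030 without neuronal control library 2). The quinone reductase Nqo1 had 18 agonist and 12 control counts, the aldehyde dehydrogenase Aldh3a1 4 and 1, and Cyp1a2 0 and 0. In exact permutation tests Cyp1a1, Ahrr and Ahr had the smallest p the design allows, 0.0286, which is 0.0971 after adjustment over the 17 tests. Tiparp had an exact p of 0.0857 and Cyp1b1 0.114.

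**Figure D3:**
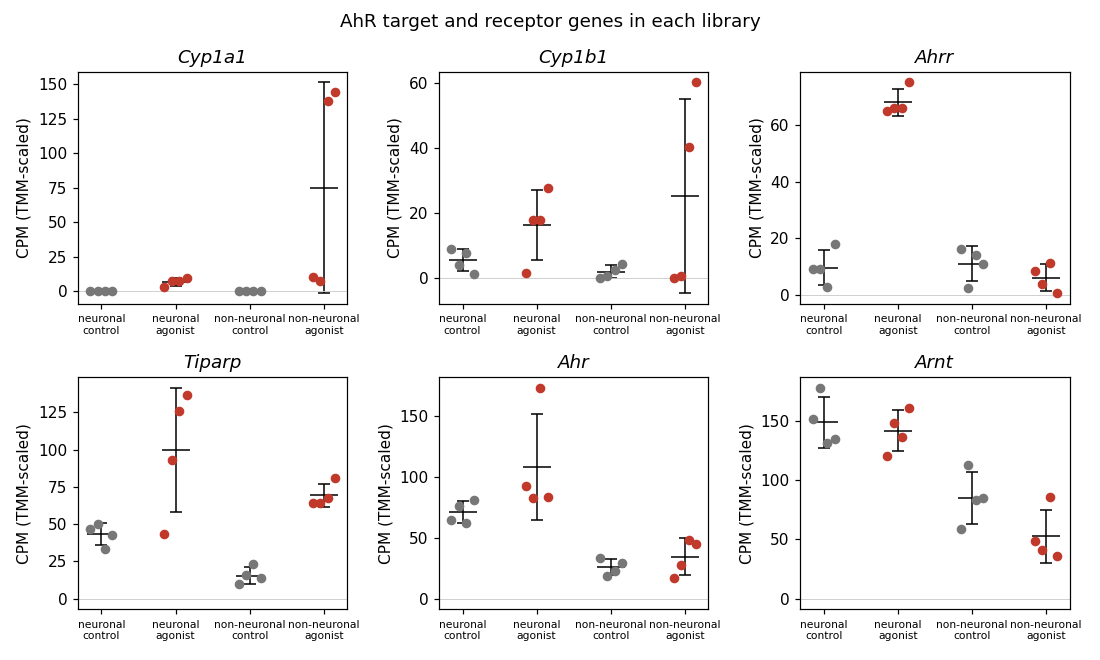
Points are single libraries and bars the mean ± SD of 4 libraries, in TMM-scaled CPM, for 6 AhR genes in the 4 groups. Neuronal Ahrr averages 68.0 CPM with agonist and 9.70 CPM with corn oil, while non-neuronal Ahrr averages 6.11 and 10.98 CPM.

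The genes with the smallest p in neuronal nuclei that did not pass included genes of varied function outside the AhR list. Specc1 (ENSMUSG00000042331, chromosome 11), a cytospin-family protein, stood at 631 ± 105 CPM with agonist against 284 ± 35.0 CPM (SD, n = 4), a log2 fold change of 1.15 (SE 0.19, adjusted p = 0.527). Abca1 (ENSMUSG00000015243, chromosome 4), the transporter that exports cholesterol from cells, stood at 208 ± 85.2 against 61.7 ± 9.27 CPM (1.75, SE 0.31, adjusted p = 0.527). Ranges of their adjusted p over alternatives were 0.00321 to 1 and 0.000597 to 1. Nphp4 stood at 40.5 ± 27.5 against 7.14 ± 2.02 CPM (2.50, SE 0.57) and Mtag2, an RNA antisense to other genes, at 27.5 ± 31.3 against 1.57 ± 0.899 CPM (4.09, SE 0.98). On the lower side, the cytokine Tnfsf18 had 3 agonist and 135 control counts, a ratio of 0.0218 with a counting interval from 0.00444 to 0.0650. Fbxo7, part of a ubiquitin ligase, stood at 608.5 ± 39.0 against 909 ± 59.0 CPM (-0.58, SE 0.15), and Fat3, an atypical cadherin, at 339 ± 79.6 against 572 ± 39.2 CPM (-0.75, SE 0.20). The kinase Itpkc stood at 1.07 ± 0.451 against 9.62 ± 4.12 CPM (-3.14, SE 0.83) and the pseudogene Ifi203-ps at 9.40 ± 7.08 against 44.3 ± 15.3 CPM (-2.23, SE 0.60). These 7 other genes had an adjusted p of 0.903 by edgeR. DESeq2 called Nphp4 (0.0129), Mtag2 (0.00955), Tnfsf18 (0.00825) and Itpkc (0.0401), and on the genes edgeR kept the first 3 of these. Ranges over alternatives reached up to 1 for each, from 0.0129, 0.00195, 0.00825 and 0.0401, and from 0.0431 for Ifi203-ps.

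Of 22 lists tested in neuronal nuclei, smooth muscle genes passed by camera, on the lower side. Of 19 such genes 16 were below 0, with a median of -0.54 (adjusted p = 0.0473) and no member called over all genes, and the adjusted p was 0.865 with an estimated correlation (range over alternatives 0.000274 to 0.865). Its smallest p-values were those of Synpo2 (-1.17, SE 0.31) and Tpm2 (-1.36, SE 0.46), an actin-binding protein and a tropomyosin. The call was lost without neuronal agonist library 2 (0.31), agonist library 3 (0.371) or control library 4 (0.597). The summed smooth muscle level was 1377 CPM with agonist and 1793 CPM with corn oil in the neuronal libraries. AhR target genes had a median of 1.21 over 5 genes, 3 of them above 0, and an adjusted p of 0.0564, or 0.638 with an estimated correlation. They passed without neuronal agonist library 1 (0.00764) and without control libraries 1 (0.000274), 2 (0.0088), 3 (0.000412) or 4 (0.0316), in a range from 0.000274 to 0.638.

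Lists of neuronal function held no called gene and did not pass in neuronal nuclei. The medians were -0.15 for 21 transmitter and peptide genes (mean 0.14, adjusted p = 0.813), 0.17 for 52 channel genes (0.756), 0.06 for 46 receptor genes (0.756) and 0.10 for 35 synaptic genes (0.756). Pan-neuronal genes had an adjusted p of 0.918. The medians of receptor, synaptic and transferase genes change sign with library size only, and those of pan-neuronal and AhR signalling genes with DESeq2 size factors. Single values were 2.88 for the dopamine-synthesis enzyme Th (SE 1.02), 0.69 for the acetylcholine-synthesis enzyme Chat and -0.77 for the peptide Vip. Immediate early genes had a median of 0.27 over 14 genes (0.756), heat shock 0.15 over 11 (0.756), clock 0.36 over 17 (0.756), glucocorticoid-responsive -0.15 over 7 (mean 0.32, 0.918), p53 target -0.30 over 9 (0.918), cholesterol synthesis -0.10 over 18 (0.588) and interferon-stimulated genes 0.72 over 11 (0.588). Oxidative stress genes had -0.08 over 12 (mean 0.17, 0.770), AhR signalling components -0.02 over 10 (mean 0.05, 0.756) and transferases 0.01 over 6 (mean -0.12, 0.756). Glia genes had -0.40 over 7 (0.161), interstitial cell genes -0.29 over 5 (mean 0.08, 0.813), fibroblast genes -0.07 over 13 (0.588), mitochondrial genes -0.22 over 12 (0.756) and ribosomal protein genes -0.34 over 32 (0.0649). Scaling moved the median of all genes from 0.08 with TMM to -0.03 with library size only.

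The agonist response in non-neuronal nuclei asks the same of the other cells of the tissue. Cyp1a1 and Serpina3n were higher with agonist. Cyp1a1 stood at 10.2, 7.65, 138 and 144 CPM in agonist libraries 1 to 4 and at 0, 0, 0.246 and 0 in control libraries. That is 1385 against 1 count, a ratio of 1457 with a counting interval from 261 to 57579. Serpina3n (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), a protease inhibitor of the acute-phase response in a family of near-identical genes, stood at 142 ± 30.8 against 6.90 ± 5.40 CPM (SD, n = 4).

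These were the only calls among 14846 genes tested by edgeR, both with an adjusted p of 0.0396. The fitted log2 fold change was 4.35 for Serpina3n (SE 0.62). A total of 715 genes had an unadjusted p under 0.05, where 742.3 are given by chance, 450 higher and 265 lower. The median SE of a log2 fold change was 1.00. DESeq2 called 27 genes higher and 113 lower, or 18 and 17 on the genes edgeR kept, no filter 88, all 4 groups in 1 fit 11, and voom 1, Serpina3n. Library size only and a mean of at least 5 CPM called 0.

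Leaving out a single library ended most of these calls. Cyp1a1 had an adjusted p of 0.263 without agonist library 3, 0.304 without agonist library 4, and 0.443, 0.325, 0.493 and 0.354 without control libraries 1 to 4 (range over alternatives 1.58e-12 to 0.493). Serpina3n had 0.0863, 0.263 and 0.199 without agonist libraries 2, 3 and 4, and 0.443, 0.325 and 0.259 without control libraries 1, 2 and 3 (range 3.39e-09 to 0.443). The log2 fold change of Serpina3n lay between 4.09 and 5.06 when each library was left out in turn. Without the libraries over 30% mitochondrial counts Cyp1a1 was called and Serpina3n had an adjusted p of 0.0635.

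The remaining AhR genes of non-neuronal nuclei did not pass. Tiparp stood at 69.2 ± 7.89 CPM with agonist and 15.4 ± 5.71 CPM with corn oil, with every agonist library above every control (2.16, SE 0.58, adjusted p = 0.739, and 0.00929 adjusted over the list alone). DESeq2 gave it 0.0185 (range over alternatives 0.0185 to 1). Cyp1b1 stood at 0, 0.403, 40.1 and 60.1 CPM in agonist libraries 1 to 4 and had 478 agonist and 32 control counts, and it was filtered out. Ahrr stood at 6.11 ± 4.74 against 10.98 ± 6.15 CPM (-0.84, SE 1.15). Ahr stood at 34.4 ± 14.98 against 25.9 ± 6.48 CPM (0.41, SE 0.65), and Arnt at 52.6 ± 22.6 against 85.2 ± 22.0 CPM (-0.69, SE 0.48). Nqo1 had a log2 fold change of 1.05 (SE 1.3), which was -0.94 without agonist library 1. Aldh3a1 had 44 counts, all in agonist library 2, against 0 in controls, and Cyp1a2 had 0 and 1. In exact permutation tests Cyp1a1 and Tiparp had the smallest p the design allows, 0.0286 (0.0971 adjusted), and Ahrr had 0.257.

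Genes with the smallest p on the lower side did not pass by edgeR. The olfactory receptor Olfr607 had 6 agonist and 497 control counts (-6.00, SE 1.26, adjusted p = 0.593). The myosin Myo3a stood at 9.04 ± 3.14 against 94.97 ± 87.6 CPM (-3.38, SE 0.74). The sodium-chloride transporter Slc12a3 had 0 against 181 counts, at least 57.4-fold lower, and the skeletal muscle myosin Myh2 0 against 164, at least 52.0-fold lower. Every non-neuronal agonist library detected fewer genes than every control library, and whether such counts of 0 reflect this was not tested. Ggcx, the carboxylase of vitamin K-dependent proteins, stood at 3.68 ± 1.11 against 37.3 ± 13.2 CPM (-3.33, SE 0.82, adjusted p = 0.705). DESeq2 on the genes edgeR kept called all 5, with an adjusted p of 4.4e-05 for Olfr607, 0.00295 for Myo3a, 0.00274 for Slc12a3, 0.0048 for Myh2 and 0.00239 for Ggcx. Slc12a3 was also called with all 4 groups in 1 fit (0.0485). Ranges over alternatives reached up to 1 for each, from 4.4e-05, 0.00288, 0.000686, 0.000938 and 0.000585.

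Glucocorticoid-responsive genes lay higher with agonist as a list in non-neuronal nuclei. All 13 tested were above 0, with a median log2 fold change of 2.14 and an adjusted p of 1.97e-08 by camera, and the adjusted p was 0.0651 with an estimated correlation (range over alternatives 3.09e-10 to 0.0651). The cell cycle inhibitor Cdkn1a stood at 70.2 ± 31.7 against 7.69 ± 4.88 CPM (3.18, SE 0.69) and Angptl4, an inhibitor of lipoprotein lipase, at 33.4 ± 26.2 against 3.46 ± 1.44 CPM (3.25, SE 1.01). Cdkn1a (0.00411) and Angptl4 (0.0353) passed when adjusted over the list alone, and no member passed over all genes by edgeR. DESeq2 on the genes edgeR kept called Cdkn1a over all genes (0.00143, range over alternatives 0.00143 to 1). Cdkn1a is also in the p53 target list, and Per1, another member, in the clock list. The transcription factor Zbtb16 had 2.18 (SE 0.79) and the kinase Sgk1 2.27 (SE 0.94). Without the libraries over 30% mitochondrial counts the median was 1.13 (adjusted p = 2.72e-05).

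Cholesterol synthesis genes lay lower. Of 18 members 15 were below 0, with a median of -0.88 (adjusted p = 0.000126), and the adjusted p was 0.0768 with an estimated correlation (range over alternatives 0.000246 to 0.0768). The members with the smallest p were the squalene synthase Fdft1 (-2.12, SE 0.74), the reductase Dhcr7 (-2.57, SE 1.04), the oxidase Msmo1 (-2.08, SE 0.91) and the demethylase Cyp51 (-1.34, SE 0.68). None passed, over all genes or over the list alone. Without the libraries over 30% mitochondrial counts the median was -0.82 (adjusted p = 0.0201).

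**Figure D4:**
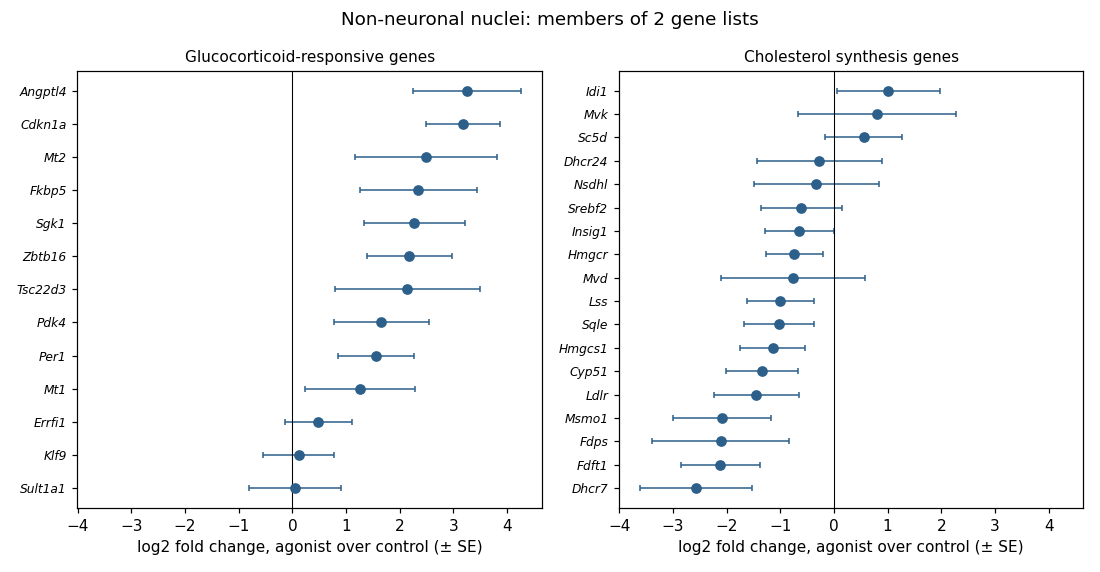
Points give the log2 fold change (agonist over corn oil) of each tested glucocorticoid-responsive and cholesterol synthesis gene in non-neuronal nuclei, 4 libraries per group, and bars its SE. All 13 glucocorticoid-responsive genes lie above 0, and 15 of 18 cholesterol synthesis genes lie below it.

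The other lists called by camera in non-neuronal nuclei lay higher, and each of these calls ended with an estimated correlation. Inflammatory mediators had 9 of 10 members above 0 and a median of 1.25 (adjusted p = 0.0015, and an adjusted p of 0.0768 with an estimated correlation, range over alternatives 0.000323 to 0.188), with Lcn2 at 2.30, the adhesion molecule Icam1 at 2.06 and the NF-kB inhibitor Nfkbia at 1.34. Interferon-stimulated genes had 16 of 19 above 0 and a median of 0.96 (0.0162, and an adjusted p of 0.278 with an estimated correlation), with Oasl2 at 2.11 and Ifit1 at 2.68. This call was lost without agonist library 3 (0.184, range over alternatives 2.72e-05 to 0.694). AhR target genes had 7 of 10 above 0 and a median of 1.01 (0.0162, and an adjusted p of 0.278 with an estimated correlation), with the glucuronosyltransferases Ugt1a6b at 2.69 and Ugt1a7c at 1.18. It was lost without agonist library 1 (0.0573) and control library 2 (0.0675, range 0.000833 to 0.278), and the median was 0.29 without the libraries over 30% mitochondrial counts (0.0367). Transferases of glutathione and glucuronic acid had 16 of 17 above 0 and a median of 1.14 (0.0162, and an adjusted p of 0.638 with an estimated correlation), with Gstm3 at 3.29 and Gsto1 at 1.89. It was lost without agonist library 1 (0.294), without control library 2 (0.106) and without the libraries over 30% mitochondrial counts (0.136 and a median of 0.38, range 0.00128 to 0.948). Scaling moved the median of all genes from 0.13 with TMM to -0.28 with library size only, and the medians of the 6 lists called moved with it. With library size only they were 1.39 for glucocorticoid-responsive, -1.39 for cholesterol synthesis, 0.92 for inflammatory, 0.35 for interferon-stimulated, 0.50 for AhR target and 0.68 for transferase genes.

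Lists of other cells did not pass in non-neuronal nuclei over all libraries. Macrophage genes had 13 of 15 above 0 and a median of 0.59 (adjusted p = 0.0832), and passed without the libraries over 30% mitochondrial counts (0.0291, range over alternatives 0.0291 to 0.367). So did blood endothelial genes (0.0164, range 0.0164 to 0.963) and mesothelial genes (0.0238, range 0.0238 to 0.963). Lymphatic endothelial genes had 0.60 over 9 genes (0.0832), smooth muscle -0.24 over 22 (0.716), mesothelial 0.38 over 7 (0.635), pericyte -0.09 over 7 (mean 0.21, 0.737) and epithelial genes 0.49 over 19 (0.826), while the summed epithelial level, mostly Muc2, was lower with agonist. Several other medians change sign with library size only, namely glia 0.10 over 14 (mean -0.0015, 0.916), interstitial cell 0.24 over 9 (0.896), fibroblast 0.03 over 20 (0.896), blood endothelial 0.16 over 17 (0.201), lymphocyte 0.01 over 12 (0.916), mitochondrial 0.53 over 13 (0.136) and ribosomal protein genes 0.39 over 32 (0.161). The sign also changes for AhR signalling components (0.30 over 12, 0.568), oxidative stress (0.52 over 13, 0.120), immediate early (0.34 over 20, 0.916), heat shock (0.21 over 13, 0.305), clock (0.05 over 19, 0.737) and transmitter genes (0.30 over 10, 0.916). p53 target genes had 0.46 over 10 (0.0832), pan-neuronal genes -0.27 over 22 (0.0832), channel genes -0.01 over 41 (0.604), receptor genes -0.16 over 41 (0.0830) and synaptic genes -0.12 over 33 (0.737).

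The difference of the agonist response between populations asks which genes respond otherwise in neurons than in the other cells. Ahrr had the smallest p among the fixed AhR genes. In the fit over all 16 libraries it stood at 57.3 ± 4.04 CPM with agonist and 8.15 ± 5.13 CPM with corn oil in neuronal nuclei, and at 7.09 ± 5.60 and 13.2 ± 7.50 CPM in non-neuronal nuclei (SD, n = 4). Its log2 difference of responses was 3.70 (SE 1.15), with an adjusted p of 0.0265 over the 7 fixed AhR genes tested and 0.0454 over the AhR target list alone. Over all genes it was 0.432 (range over alternatives 0.064 to 1). The values of the other fixed genes did not pass and were -2.23 for Cyp1a1 (SE 6.25), -2.08 for Cyp1b1 (SE 1.87), -0.91 for Tiparp (SE 0.65), -0.47 for Nqo1 (SE 2.05), 0.24 for Ahr (SE 0.65) and 0.65 for Arnt (SE 0.51). The Cyp1a1 value does not tell which response is larger. Its control mean was 0 CPM in neuronal and 0.0616 CPM in non-neuronal nuclei in the fits of single populations. Without non-neuronal agonist library 1 Nqo1 had 1.48, and without neuronal agonist library 3 Ahr had -0.092.

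No gene passed over all 18566 genes tested by edgeR, in which the smallest adjusted p was 0.162 and 1484 genes had an unadjusted p under 0.05, where 928.3 are given by chance. DESeq2 called 150 genes, or 103 on the genes edgeR kept, and voom called 0. Without non-neuronal agonist library 3 edgeR called 9, the neuronal marker Elavl4 among them (3.08, adjusted p = 0.0379). Without the libraries over 30% mitochondrial counts it called 7. The median SE was 1.42. Svep1, an extracellular matrix protein, had the smallest p, at 0.252 and 3.87 CPM in neuronal agonist and control nuclei and 147 and 73.9 CPM in non-neuronal ones (-4.76, SE 0.88, adjusted p = 0.162, range over alternatives 0.00149 to 0.991). The glycosyltransferase Galnt1 had -2.41 (SE 0.57) and the lectin Chodl -4.49 (SE 1.09). Cstb, a protease inhibitor, had 0 and 2.17 CPM in neuronal and 67.7 and 0.774 CPM in non-neuronal nuclei, and passed without non-neuronal agonist library 3 (adjusted p = 0.0421) and without the libraries over 30% mitochondrial counts (0.0252, range 4.1e-07 to 0.991). Naip1, of a family of near-identical genes, had 0 and 2.003 CPM against 76.7 and 53.9 CPM. On the higher side stood Dnah1 (34.3 and 24.6 CPM against 0 and 5.41), Nphp4 (34.1 and 6.01 against 0 and 3.13), Trpc7 (21.5 and 14.4 against 0 and 7.07), the netrin receptor Unc5a (59.7 and 24.7 against 0.181 and 13.7) and Slc12a3 (7.33 and 7.98 against 0 and 14.3). None of these passed in the fit as reported, and over alternatives the lowest adjusted p was 0.00332 for Galnt1, 0.00721 for Chodl, 0.00677 for Naip1, 0.000284 for Dnah1, 0.000518 for Nphp4, 0.00129 for Trpc7, 0.000268 for Unc5a and 0.000691 for Slc12a3, with the highest at 0.991 or 1. Dnah1, Nphp4 and Trpc7 were also among the genes named above as highest in neuronal nuclei of agonist mice. The summed pan-neuronal level of non-neuronal libraries was 616 ± 302 CPM with corn oil and 446 ± 209 CPM with agonist. Whether neuronal RNA left in the non-neuronal libraries gives these differences was not tested.

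By camera, 6 lists differed in response, and none passed with an estimated correlation or exceeded every other split drawn. Glucocorticoid-responsive genes lay toward the non-neuronal side (median -0.34 over 14 genes, mean -0.95, adjusted p = 0.000488, and an adjusted p of 0.0725 with an estimated correlation, range over alternatives 2.74e-05 to 0.254), with Cdkn1a at -3.44 (SE 1.37) and the clock gene Per1 at -2.15. Cholesterol synthesis genes lay on the other side (12 of 18 above 0, median 0.81, adjusted p = 0.00611, and an adjusted p of 0.170 with an estimated correlation), with Fdft1 at 2.40 (SE 0.76). This call was lost without the libraries over 30% mitochondrial counts and neuronal agonist library 1 (0.0722, range over alternatives 0.00194 to 0.254). Inflammatory mediators (-0.90, 0.00762, and an adjusted p of 0.0725 with an estimated correlation) included Lcn2 at -5.58 (SE 2.05) and Il1b at 5.65 (SE 2.54), and Il1b had -0.14 without neuronal agonist library 3. The list was lost without non-neuronal agonist library 4 (0.0513, range 0.00398 to 0.401).

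Ribosomal protein genes (-0.62, 0.00762), transferases (-0.98, 0.0141) and lymphatic endothelial genes (-0.97, 0.0286) also lay toward the non-neuronal side in the difference, each with an adjusted p of 0.494 with an estimated correlation. The ribosomal call was lost without non-neuronal agonist library 4 (0.149, range over alternatives 0.000629 to 0.877). The transferase call was lost without neuronal agonist library 3 (0.0505), non-neuronal agonist library 1 (0.16) or non-neuronal control library 2 (0.0678), and without the libraries over 30% mitochondrial counts (0.083) or these and neuronal agonist library 1 (0.188), in a range from 0.00259 to 0.877. The lymphatic call, in which the receptor Lyve1 had -3.02 (SE 0.87), was lost without neuronal agonist library 2 (0.0702), neuronal control library 4 (0.0983), non-neuronal agonist libraries 2 (0.114), 3 (0.0882) or 4 (0.0526), or non-neuronal control library 2 (0.149), in a range from 0.00814 to 0.877. AhR target genes had a median of -0.96 over 12 genes (mean -0.39, adjusted p = 0.302) and pan-neuronal genes 0.34 over 30 (0.0868). Scaling moved the median of all genes from 0.04 with TMM to 0.28 with library size only. Across 11697 genes the agonist responses of the 2 populations had a Pearson correlation of 0.0381 and a Spearman correlation of 0.0440, and genes are not independent replicates.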

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

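The tests of carry-over from other cells, of the share of single cell types, of list means without the libraries over 30% mitochondrial counts, and of the mean of Ahrr and Tiparp over other splits were chosen after their results were seen.

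A single library stood far from the other 3 of its group in 10 of 143 groups checked, where chance gives 7.15. In non-neuronal agonist library 4 ribosomal protein genes took 0.625% of the counts, against 0.260% to 0.298% in the others. In non-neuronal agonist library 3 Elavl4 stood at 76.7 CPM (others 1.75 to 3.07). In non-neuronal control library 4 Elavl4 stood at 51.8 CPM (others 20.2 to 23.3) and Myh11 at 7413 CPM (others 2787 to 3017). Neuronal agonist library 1 held 1.50 CPM of Cyp1b1 (others 17.7 to 27.6). Neuronal agonist library 3 held 173 CPM of Ahr (others 82.8 to 92.5). Neuronal agonist library 4 held 75.0 CPM of Ahrr (others 64.9 to 66.1), 475.0 CPM of Specc1 (others 659.9 to 699.7), 68.1 CPM of Actg2 (others 16.2 to 19.3) and 4.75 CPM of Asic1 (others 23.4 to 24.5). Ahrr also differed between populations in its agonist response, by 3.70 on the log2 scale.

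Chance is argued against for the gene counts between populations, and cannot be excluded for the difference of responses. In control mice the real split called 3876 genes and every other split of the libraries 0, and in agonist mice 1918 against at most 1. Only 1 of the 35 splits, the real one, gave as many in each, which is the smallest share the design allows. Every other split mixes both populations within a group, which widens the spread, so the size of the margin carries no weight. By number of lists called, another split reached 20 against 21 in control mice and 22 against 23 in agonist mice. In non-neuronal nuclei the agonist split called 2 genes, which 1 of 35 splits reached, against at most 1 elsewhere. That margin is 1 gene, so the count carries little weight. In the simulated comparison 2 unchanged genes were among 30 called, which does not tell how many of 2 calls are false. With any 1 of 5 libraries left out 0 genes passed. A smaller group detects less, and the log2 fold change of Serpina3n changed little, as given above, so these losses do not decide on chance. For the difference of responses 1484 genes had an unadjusted p under 0.05, 24 of 100 splits gave as many, and the highest other gave 1957. Nor can chance be excluded for the 6 lists called in that difference, as the real split was the highest for 0 of 30 lists. The glucocorticoid list, for one, had a mean of 0.952 in size against at most 2.30 elsewhere, with 34 of 100 splits as large, and the lymphatic list 1.23 against 1.70 with 12. For the smooth muscle list in neuronal nuclei the mean was 0.507 in size against at most 0.983, with 14 of 35 splits as large.

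No gene passed by edgeR for the agonist in neuronal nuclei, while DESeq2 called 24 or, on the genes edgeR kept, 9, and voom called 3. Chance cannot be excluded for the 711 genes with an unadjusted p under 0.05, since 10 of 35 splits gave as many, and the highest, 1823, sets agonist libraries 1 and 2 and control libraries 2 and 3 against the rest and called 0 genes itself, and what sets these libraries apart was not tested. Spread from neuronal agonist library 1, which has the fewest detected genes (17293), stays open as a reason, since 0 genes passed without it but 3 libraries against 4 detect less, the smallest adjusted p moved from 0.527 to 0.0671 (range over left-out libraries 0.0671 to 1.00), and voom weighted it at 0.151. The mean of the Ahrr and Tiparp differences was 2.02 on the log2 scale against at most 1.56 in other splits, reached by 1 of 35, but they were picked for passing over their list. A response limited to few genes, and an agonist effect hidden by the spread of libraries, may hold and stay open.

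Ahrr stood higher with agonist in neuronal nuclei and not in non-neuronal nuclei. An average mix of non-neuronal nuclei in the neuronal sort, which the EGFP gate should remove, is argued against as the source of Ahrr. Its mean level in non-neuronal agonist libraries lies below every neuronal agonist library, so no share of such a mix could reach them. A single cell type rich in Ahrr that passes the gate more often is not covered by a mean, and stays open. The carry-over shares of 11 other-cell lists therefore decide nothing further for Ahrr. The largest share plus 2 SE, that of the interstitial cell list, gives 13.8 CPM of Ahrr by library size. The lowest neuronal agonist library holds 48.7 CPM. With TMM over the agonist libraries these values are 11.6 and 47.9. The shares of these lists ran from 1.16% for epithelial to 29.9% for fibroblast genes, and 143% for interstitial cell genes. The interstitial list holds genes such as Etv1, at 318 CPM in neuronal and 156 CPM in non-neuronal agonist nuclei with TMM. By library size its bound is 137 CPM for Tiparp against a lowest library of 32.7, and 241 CPM for Cyp1a1 against 2.26. With TMM these are 97.0 against 32.1 and 159 against 2.22. The interstitial share was 143% by library size and 95.6% with TMM (SE 16.3), and its gene Etv1 stood higher in neuronal nuclei. Such a share cannot be read as carry-over alone, so that list decides nothing for either gene. Fibroblast genes, the next largest share, give a bound of 32.4 CPM for Tiparp, or 23.7 with TMM. Both lie below every neuronal agonist library, the first narrowly. This argues only against an average mix of the remaining cells as the whole source of the Tiparp level. It does not address the rise of Tiparp with agonist, so carry-over as a source of that rise stays open. For Cyp1a1 fibroblast genes give 53.1 CPM, or 36.4 with TMM, so Cyp1a1 cannot be told apart from carry-over in neurons. Doubtful libraries are argued against as well, as the difference was 3.64 (SE 1.29) without the libraries over 30% mitochondrial counts and neuronal agonist library 1, so a stronger response of Ahrr in neurons may hold, as a hypothesis that did not pass over all genes.

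Glucocorticoid-responsive genes lay higher and cholesterol synthesis genes lower with agonist in non-neuronal nuclei, 2 of 30 lists tested. Taken alone, each list exceeded every other split (mean of 1.77 against at most 1.47, and 0.878 against at most 0.749 in size, reached by 1 of 35), as did 5 of the 30 lists, AhR, p53 and macrophage included, where chance gives 0.857, but 12 of 35 splits called at least 6 lists and the highest 16, so chance cannot be excluded for their number. Libraries over 30% mitochondrial counts are argued against as the whole cause, with medians of 1.13 and -0.82 without them, though the first was 2.14 with them. A change in the share of 1 cell type cannot be told apart from either pattern, because the summed epithelial level, mostly Muc2, differed by -1.23 on the log2 scale by library size (SE 0.56), by -0.84 with TMM (SE 0.66) and in its members' mean by 0.32 (SE 0.32), lymphocyte genes had a mean of -2.12 without those libraries and 0.19 with them, and mesothelial genes reached 1.86 with 2 SE without them (mean 0.91) against a glucocorticoid mean of 1.43. A response to the agonist, a shift of cells and the spread among few libraries may each be the source and stay open, with adjusted p = 0.0651 and 0.0768 with an estimated correlation.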

How the results depend on the processing

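DESeq2 on the genes edgeR kept and the settings without doubtful libraries were added after seeing the data. For the agonist in neuronal nuclei, against 0 genes, DESeq2 called 24, DESeq2 on the genes edgeR kept 9, no filter 152 and voom 3, and every other alternative and left-out library 0. In non-neuronal nuclei, against 2, DESeq2 called 140, its run on kept genes 35, no filter 88, all 4 groups in 1 fit 11, voom 1, library size only 0, a mean of 5 CPM 0, and the libraries over 30% mitochondrial counts left out 1. Left-out libraries gave 0 to 2, with 0 without agonist libraries 3 or 4 or control libraries 1, 2 or 3. For the difference, against 0, DESeq2 called 150, its run on kept genes 103, no filter 110, and the libraries over 30% mitochondrial counts left out 7. Left-out libraries gave 0 to 9, the most without non-neuronal agonist library 3. Between populations in control mice DESeq2 called 6716 against 3876, and left-out libraries gave 3399 to 4735. In agonist mice, against 1918, DESeq2 called 4340, its run on kept genes 2953, no filter 3324, voom 2910 and all 4 groups in 1 fit 4590, and left-out libraries gave 1553 to 2064. A correlation estimated per list kept 17 of 57 list calls. The cause of these differences was not tested.

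Signs turned for 4 fixed AhR values and 1 inflammatory gene, none of them called, and the cause was not tested. Arnt in neuronal nuclei ran from -0.14 to 0.030 over left-out libraries. Nqo1 in non-neuronal nuclei ran from -0.94 to 2.07, and was -1.64 without the libraries over 30% mitochondrial counts. For the difference, Nqo1 ran from -1.75 to 1.48, and was 2.11 without those libraries and 0.85 without neuronal agonist library 1 as well. Ahr ran from -0.092 to 0.39, with -0.24 and -0.26 under the same settings. Il1b ran from -0.14 to 6.20.

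Replicate numbers were not taken as pairs. Correlations of libraries with the same number ran from -0.127 to 0.211, and 7 of 16 such pairs, 4 in each of 4 comparisons, exceeded the highest pair with another number, where chance gives 4. Number 4 did so in all 4 comparisons (0.211, 0.0240, 0.0565 and 0.0911), and numbers 1 to 3 in 3 of 12, so a link among the libraries numbered 4 stays open. With the number as a block the counts were 0, 2, 0, 3731 and 1941, with 57 list calls. Library size only turned the balance between populations to 55.4% higher in control and 67.2% in agonist mice, from 46.7% and 48.9%. At this depth the upper 95% counting limit of a gene with 0 counts in a library is about 0.612 to 1.13 CPM there.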

Other observations

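Genes of this part were chosen after their values were seen. Muc2, the main mucin of goblet cells, lay lower on average with agonist in both populations. It stood at 2204 ± 1016 CPM against 5382 ± 4262 CPM in non-neuronal nuclei (log2 fold change -1.29, SE 0.55) and at 7.85 ± 3.36 against 39.5 ± 33.8 CPM in neuronal nuclei (-2.32, SE 0.69), each mean over 4 libraries, and it passed in neither by edgeR (adjusted p over alternatives from 0.0458 in neuronal and 0.450 in non-neuronal nuclei, up to 1 in each). Whether its low neuronal level is carry-over from non-neuronal nuclei was not tested. In non-neuronal nuclei the summed epithelial level, mostly Muc2, overlapped between treatments (1198 to 4084 CPM with agonist, 1743 to 11653 CPM with corn oil). The epithelial list had a median log2 fold change of 0.49 there, on the higher side. F13a1, a coagulation factor subunit made by tissue macrophages, stood at 62.2 ± 28.9 CPM with agonist against 8.29 ± 3.40 CPM in non-neuronal nuclei (2.90, SE 0.69), with an adjusted p of 0.593 over all genes (0.00961 by DESeq2, range over alternatives 0.00463 to 1) and 0.0101 adjusted over the macrophage list alone. The complement gene C3 had 2.37 (SE 0.65) there, with 0.0429 adjusted over the fibroblast list alone (range over all genes and alternatives 0.0182 to 1). Nfe2l2, which encodes the transcription factor NRF2, stood at 70.8 ± 26.9 against 23.7 ± 4.82 CPM in neuronal nuclei (1.58, SE 0.39), with an adjusted p of 0.903 over all genes (0.0495 by DESeq2, range over alternatives 0.0495 to 1) and 0.0179 adjusted over its list alone.

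The non-neuronal agonist libraries differed among themselves in the induced enzymes. Cyp1a1 stood at 10.2 and 7.65 CPM in libraries 1 and 2 and at 138 and 144 CPM in libraries 3 and 4, and Cyp1b1 at 0 and 0.403 against 40.1 and 60.1 CPM. Mitochondrially encoded genes took 42.8% and 33.3% of the counts in libraries 1 and 2 and 21.8% and 10.3% in libraries 3 and 4. Tiparp, at 69.2 ± 7.89 CPM over the 4 libraries, did not part them in this way. Why the libraries differ was not tested.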
